A study of Mus musculus with 72 samples.

How the data were processed

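The samples were livers of male wild-type mice of 4 inbred strains, named per the labels C3HeB/FeJ (C3H below), C57BL/6NTac (B6N), C57BL/6J (B6J) and 129P2/OlaHsd (129). The mice were housed singly. At sampling they were random-fed. They had received a high-fat diet (HFD) for 21 days or served as controls, which per the labels' protocols ate a low-fat diet for no more than 21 days. Their treatment label reads none, so whether every control ate that diet was not settled, and HFD effects are differences from these controls. Total RNA was isolated with a column kit including a DNase step, amplified and labelled as sense-strand cDNA and hybridised to Affymetrix Mouse Gene ST arrays. The deposited values were log2 expression values per probe set that the authors made with the RMA algorithm, run in Affymetrix Expression Console 1.1 per the submitters' processing notes. RMA subtracts background, quantile-normalises and summarises the probes of each set. Whether all arrays were normalised together was not given in the sources used here.

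The value table held 35556 probe sets on 72 arrays. No 2 columns were identical, and the highest correlation of 2 arrays of a group was 0.9954. The array medians fell into 3 ranges that followed strain, 6.46 to 6.65 in 129, 4.51 to 4.67 in B6J and B6N together, and 3.10 to 3.28 in C3H. Quantile normalisation leaves arrays with like medians, so the values were read as 3 separately normalised sets. Levels were therefore compared only within a set. Of the comparisons of control livers between strains, only B6N against B6J was run. The other 5 pairwise control comparisons and the test of any strain difference among controls, which had been planned, were not run. A diet effect is a difference within a set, and interactions compare such differences, so these were kept. Fold changes of the sets can be compressed unequally, which limits interactions that rest on effects of 1 sign and different size. The 3 sets also differed in residual spread, with median residual SDs of 0.170, 0.196 and 0.229 (129, B6, C3H).

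Gene names came from the platform annotation, updated through Entrez identifiers. 21789 probe sets carried 1 gene symbol, 1621 carried several and 12146 were not listed there, and 21698 of those with 1 symbol matched the gene table by identifier. Probe sets with several symbols or none were not named. Of the 19938 genes tested, 999 had more than 1 probe set, and the probe set with the highest mean over all arrays was used. Probe sets of close family members (Cyp2b, Cyp3a, Cyp4a, Gstm) can share signal, which is a limit on every value given for these genes. No genome coordinates were used. Without detection calls, a level below the array medians cannot be told from background, so folds that rest on such a level have an uncertain size and no bound was set. Arrays give no read depth, and the number of arrays limits the precision.

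Each gene was fitted in limma 3.58.1 (R 4.3.3) with 1 mean for each of the 8 groups over all 72 arrays, which left 64 residual degrees of freedom and 1 estimate of the spread shared by all groups. Contrasts were the HFD effect in each strain, its unweighted mean over the 4 strains, the 6 pairwise differences of HFD effects between strains, the moderated F test of any such difference, and B6N against B6J controls. Tests were two-sided and moderated across genes (eBayes), with Benjamini-Hochberg adjustment over all genes of a contrast. A gene was called at an adjusted p under 0.05. Every adjusted p below comes from this limma fit or from its gene set tests, except those of permutation tests, which are named as such. Values are log2 fold changes ± standard error (SE), or group means ± SD. Nothing in the labels says which samples share a cage, litter or day, so p-values measure the spread between these samples. In B6J, B6N and C3H, controls were 15 to 17 weeks old and HFD mice 17 weeks, so age went partly with diet. All 129 mice were 17 weeks old.

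On data simulated for the same arrays with 200 changed genes per contrast, the fit recovered 92%, 81%, 85% and 95% of 1.5-fold changes in 129, B6J, B6N and C3H. It recovered 96%, 100%, 96% and 100% of 2-fold changes. The share of calls that were false was 5.53%, 6.70%, 6.22% and 5.34%. The simulated noise was independent between arrays, with the same SD of a gene in every group. It held neither the unequal spread of the sets nor the structure among arrays described below. These shares may therefore not hold for the real arrays.

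A total of 29 gene lists, 19 of liver pathways and 10 of cell type markers, was fixed together with the comparisons, the tests, the alternative settings and the rule for named genes before the data were examined. The pathway lists were fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and ketogenesis, lipid droplet proteins, fatty acid uptake and lipoprotein handling, bile acid synthesis and transport, glutathione and antioxidant defence, cytochrome P450 drug metabolism, male-biased and female-biased liver genes, glucose and insulin metabolism, amino acid catabolism and urea cycle, endoplasmic reticulum stress response, oxidative phosphorylation, peroxisome biogenesis, circadian clock, acute phase response, interferon response and antigen presentation, and cell cycle. The cell type lists were markers of macrophages and Kupffer cells, lymphocytes, stellate cells and matrix, endothelium, bile duct, adipocytes, pancreatic acinar cells, red blood cells, skeletal muscle and mature hepatocytes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and contrasts of a family. Each was repeated with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Over the 145 tests of HFD effects, camera called 73, camera with an estimated correlation 29 and fry 35. A member count given as adjusted over the list alone used Benjamini-Hochberg within that list. The text names genes by the fixed rule, which takes the largest called changes in each direction per contrast and the called list members with the largest changes. It also takes the label check genes Nnt and H2-Ea.

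The replicate numbers of control and HFD arrays were checked for pairing by the correlation of residuals between arrays of the same number. In B6N all 8 pairs lay above 0.1 (0.101 to 0.462), which by the rule fixed in advance pairs these samples, although no label says what a number stands for. Pairs above 0.1 numbered 6 of 7 in 129 (-0.22 to 0.296), 5 of 7 in B6J (-0.29 to 0.500) and 1 of 8 in C3H (-0.27 to 0.185). HFD arrays that correlated best with the control of their own number numbered 1 in 129, 2 in B6J, 2 in B6N and 0 in C3H. The residuals of the B6 arrays split along a first component with 29.4% of their variance, and the pairing in B6N coincided with this split. Its parts held 4 and 4 B6J controls, 5 and 2 B6J HFD arrays, 4 and 4 B6N controls, and 3 and 5 B6N HFD arrays. The split was found in the data and no label names it. In every B6J and B6N group, part 1 held the lower replicate numbers and part 2 the higher. The pairing by number in B6N therefore cannot be told apart from this split.

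Alternatives tried were quantile normalisation over all arrays, centring on array medians, genes above the median level only, every probe set as a test, the mean of all probe sets of a gene, a variance trend with robust moderation, array weights, a fold change of at least 1.5, only the compared groups in the fit, the replicate number as a block within strain, leaving out each array in turn, and draws of 8 of the 18 C3H controls. Added after seeing the data were the B6 split as a block and within its parts, the acinar gene level as a covariate, both together, the fit without arrays that stand apart, and the main axis of the C3H controls as a covariate.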

Results

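Liver gene expression was measured on 72 arrays from single-housed male mice of 4 inbred strains, each fed an HFD for 21 days or kept as controls. The groups held 8 control and 7 HFD arrays in 129, 8 and 7 in B6J, 8 and 8 in B6N, and 18 and 8 in C3H. The design asks how HFD changed liver mRNA in each strain, which changes the strains shared, and which differed between them. Values were normalised log2 probe set signals, comparable within 129, within the B6 strains and within C3H.

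Genes that mark the strains were examined first. Nnt, which encodes the mitochondrial transhydrogenase and is deleted in part in C57BL/6J, had a mean log2 value of 7.88 ± 0.154 in B6J controls (SD, n = 8). In B6N controls it was 9.02 ± 0.368 (n = 8). H2-Ea, an MHC class II chain that the H2-b haplotype of the B6 and 129 strains does not express, lay 1.73 ± 0.491 log2 units above the array median in C3H controls (n = 18) and 1.93 ± 0.248 above it in C3H HFD livers (n = 8). In the other groups its mean lay below the median, between -1.14 and -1.57. No group's mean went against its strain label.

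Pancreatic acinar genes, which encode digestive enzymes, varied widely between livers of 1 group. The mean log2 value of the 16 measured genes ran from 6.48 to 11.28 in 129 controls and from 6.43 to 12.34 in 129 HFD livers. In B6J it ran from 4.82 to 11.17 in controls and from 4.65 to 10.29 on HFD, the former a range of 81.6-fold. The ranges were narrower in B6N (4.44 to 6.22 and 4.70 to 7.70) and in C3H (3.36 to 6.87 and 3.35 to 6.02). HFD and control means differed by 0.561 in 129, 0.325 in B6J, 1.23 in B6N and -0.22 in C3H. Permutation tests (two-sided, exact) gave p = 0.607, 0.766, 0.0135 and 0.67, and Benjamini-Hochberg adjusted values of 0.766, 0.766, 0.054 and 0.766. Within the 2 parts into which the B6 arrays split, the difference was 1.5 and 0.947 in B6N (exact p = 0.0286 and 0.206) and 1.24 and -0.698 in B6J (0.381 and 0.667).

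**Figure D1:**
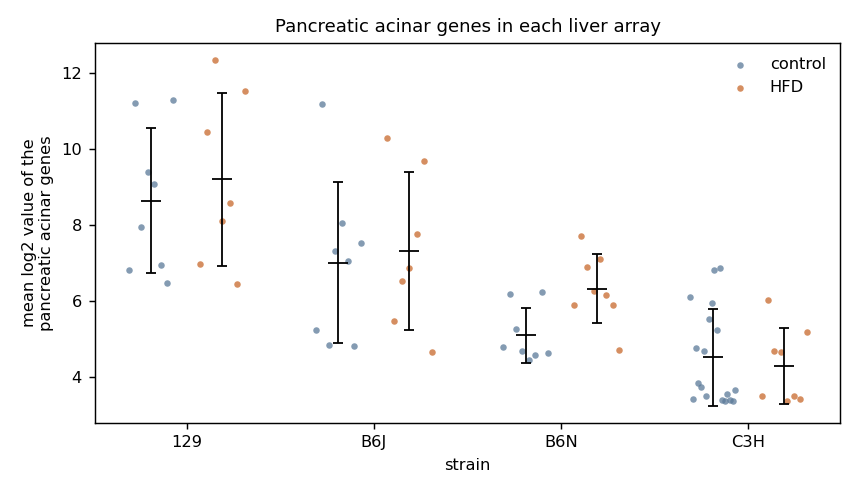
Mean log2 signal of 16 pancreatic acinar genes in each liver array (points), by strain and diet, with group mean and SD (bars). Levels are comparable within 129, within the B6 strains and within C3H. In B6N, HFD arrays averaged 6.32 and controls 5.09.

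Averaged over the 4 strains, HFD raised genes of fatty acid oxidation and lipid storage and lowered genes of glutathione and antioxidant defence and amino acid breakdown. Mfsd2a, a lysophospholipid transporter, rose 4.77-fold (95% interval 3.64 to 6.25). Cyp4a14, which hydroxylates fatty acids and is a target of the receptor PPARα, rose 4.65-fold (3.37 to 6.40), and Vnn1, a pantetheinase and PPARα target, rose 4.09-fold (3.45 to 4.85). Rgs16, a regulator of G protein signalling, Cyp2b9, a P450 enzyme, and Cyp4a31 rose by log2 values of 1.89 ± 0.24, 1.66 ± 0.20 and 1.39 ± 0.14. The Cyp2b9 mean came from B6N and C3H (3.02 and 3.49), against 0.07 and 0.04 in 129 and B6J. Apoa4, a lipoprotein component, Abcd2, a peroxisomal fatty acid transporter, Dio1, which converts thyroid hormone, and Fabp2, a fatty acid binding protein, rose by 1.36 ± 0.07, 1.34 ± 0.15, 1.30 ± 0.12 and 1.19 ± 0.11.

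Cyp7a1, the rate-limiting enzyme of the classic bile acid pathway, fell 2.51-fold (1.91 to 3.30), the largest mean decrease among called genes. Etnppl, which degrades phosphoethanolamine, fell 2.34-fold (2.02 to 2.70), and Cyp2c55, a P450 enzyme, fell 2.15-fold (1.87 to 2.47). Csad, an enzyme of taurine synthesis, fell 2.14-fold, and Acmsd, which draws tryptophan metabolites away from NAD synthesis, fell 1.98-fold. Slc13a2, a citrate and dicarboxylate carrier, Ddc, a decarboxylase of aromatic amino acids, Gstm3, a glutathione transferase, and Cyp3a44, a P450 enzyme, had mean changes of -0.90 ± 0.08, -0.87 ± 0.09, -0.86 ± 0.09 and -0.85 ± 0.08. Cyp3a44 fell in 129, B6J and B6N but rose in C3H (0.53). Of 19938 genes, 630 changed in the mean effect, 403 higher and 227 lower. Most changes were small: 66 were called with a mean change of at least 1.5-fold.

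Of the 35 measured genes of fatty acid oxidation and ketogenesis, 29 rose and none fell in the mean effect (33 adjusted over the list alone), with a median log2 change of 0.44 and a camera adjusted p of 3.6e-88. Cyp4a10 (1.15 ± 0.12) was among them. Of 19 lipid droplet genes 6 rose (8 adjusted over the list alone; camera adjusted p = 7.7e-13), among them Mgll, the monoacylglycerol lipase (0.85 ± 0.07), G0s2, an inhibitor of triglyceride lipase (0.75 ± 0.12), and the droplet coat gene Plin2 (0.55 ± 0.06). Of 23 genes of fatty acid uptake and lipoprotein handling, 8 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 2.5e-10). The fatty acid translocase Cd36 rose by 0.78 ± 0.13, and Fabp5 was the member that fell (-0.89 ± 0.13). Of 17 peroxisome genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 3e-07), led by the peroxisome division gene Pex11a (0.57 ± 0.07). Of 25 macrophage and Kupffer cell markers 6 rose (13 adjusted over the list alone; camera adjusted p = 3e-10), among them Adgre1, which encodes F4/80 (0.43 ± 0.10), and Cd5l, a secreted Kupffer cell protein (0.41 ± 0.08). Both had a positive change in all 4 strains. The largest changes of these markers were 0.31 (Marco) and -0.27 (Cd74) in B6N. In C3H they were -0.30 (Mpeg1) and 0.22 (Clec4f), and none of these was called.

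Of 35 genes of glutathione and antioxidant defence 10 fell and none rose, against 16 lower and 2 higher adjusted over the list alone (camera adjusted p = 6.9e-17). The transferases Gsta4 (-0.80 ± 0.05), Gstp1 (-0.65 ± 0.06) and Gstm6 (-0.55 ± 0.06) fell. Of 25 male-biased liver genes 10 fell (14 adjusted over the list alone; camera adjusted p = 2.6e-16), among them the complement gene C8b (-0.50 ± 0.06) and Cyp7b1, an oxysterol hydroxylase (-0.49 ± 0.09). Of 29 genes of amino acid catabolism and the urea cycle 9 fell (14 adjusted over the list alone; camera adjusted p = 1.2e-16), among them Cth, of cysteine synthesis (-0.53 ± 0.06), Hal, of histidine breakdown (-0.42 ± 0.06), and Prodh, of proline breakdown (-0.33 ± 0.06). All of these 8 lists were also called with an estimated correlation, at adjusted p = 6.7e-08, 0.00012, 0.0015, 0.02, 0.0061, 0.0015, 0.0022 and 0.017 in the order given. With an estimated correlation, the amino acid call was lost with the replicate block (adjusted p = 0.059) and the peroxisome and macrophage calls with bright genes only, those above the median level (0.077 and 0.06).

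In 8 further lists the camera call in the mean effect was lost with an estimated correlation. Fatty acid and triglyceride synthesis had 6 members higher and 2 lower of 24 (13 and 2 adjusted over the list alone; camera adjusted p = 1e-05 and adjusted p = 0.35 with an estimated correlation). The desaturase Fads2 (0.82 ± 0.09) and the elongase Elovl5 (0.51 ± 0.08) rose, and Acss2, which makes acetyl-CoA from acetate, fell (-0.45 ± 0.09). The circadian clock list had 7 members higher and 1 lower of 19 (9 and 2 adjusted over the list alone; 0.00022 and adjusted p = 0.12 with an estimated correlation). Its output gene Dbp was higher (0.67 ± 0.18) and the activator Arntl lower (-0.50 ± 0.13), and neither call held with array weights (adjusted p = 0.11 and 0.072). Of 26 P450 genes of drug metabolism 2 were higher and 6 lower (2 and 9 adjusted over the list alone; 0.00047 and adjusted p = 0.17 with an estimated correlation), and of 22 female-biased genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone; 0.002 and adjusted p = 0.095 with an estimated correlation).

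Cholesterol synthesis had 1 member lower of 20 (3 adjusted over the list alone; camera adjusted p = 0.0014 and adjusted p = 0.48 with an estimated correlation), and mature hepatocyte markers had 2 lower of 18 (2 adjusted over the list alone; 0.0037 and adjusted p = 0.38 with an estimated correlation). Oxidative phosphorylation had 0 of 45 members called by limma (0 adjusted over the list alone, 2 at unadjusted p under 0.05; 0.012 and adjusted p = 0.54 with an estimated correlation), and the acinar list 0 of 16 (0 adjusted over the list alone, 0 unadjusted; 0.0073 and adjusted p = 0.68 with an estimated correlation). Oxidative phosphorylation genes shifted by a median of -0.02.

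The other 13 lists were not called in the mean effect. Bile acid synthesis and transport had 3 members higher and 4 lower of 24 (4 and 6 adjusted over the list alone; camera adjusted p = 0.21). The sterol exporter gene Abcg5 was higher (0.41 ± 0.08) and the bile salt and anion carrier Slco1a4 lower (-0.53 ± 0.10). The acute phase list had 4 higher and 3 lower of 26 (5 and 4 adjusted over the list alone; 0.53), with the siderophore binder Lcn2 higher (0.72 ± 0.11) and the orosomucoids Orm1 (-0.49 ± 0.06) and Orm2 (-0.54 ± 0.13) lower. Glucose and insulin metabolism had 3 higher and 1 lower of 21 (3 and 1 adjusted over the list alone; 0.099), among them the glycogen synthase gene Gys2 (0.37 ± 0.08). Endoplasmic reticulum stress had 2 lower of 27 (2 adjusted over the list alone; 0.44), stellate cell markers 2 higher of 27 (3 adjusted over the list alone; 0.25), and the lists of cell cycle, lymphocyte, endothelial and adipocyte genes 1 higher each (1, 2, 1 and 1 adjusted over the list alone; 0.7, 0.099, 0.58 and 0.42). Limma called 0 members, also adjusted over the list alone, of the interferon, bile duct, red blood cell and skeletal muscle lists (6, 0, 0 and 0 at unadjusted p under 0.05; 0.12, 0.58, 0.59 and 0.42).

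**Figure D2:**
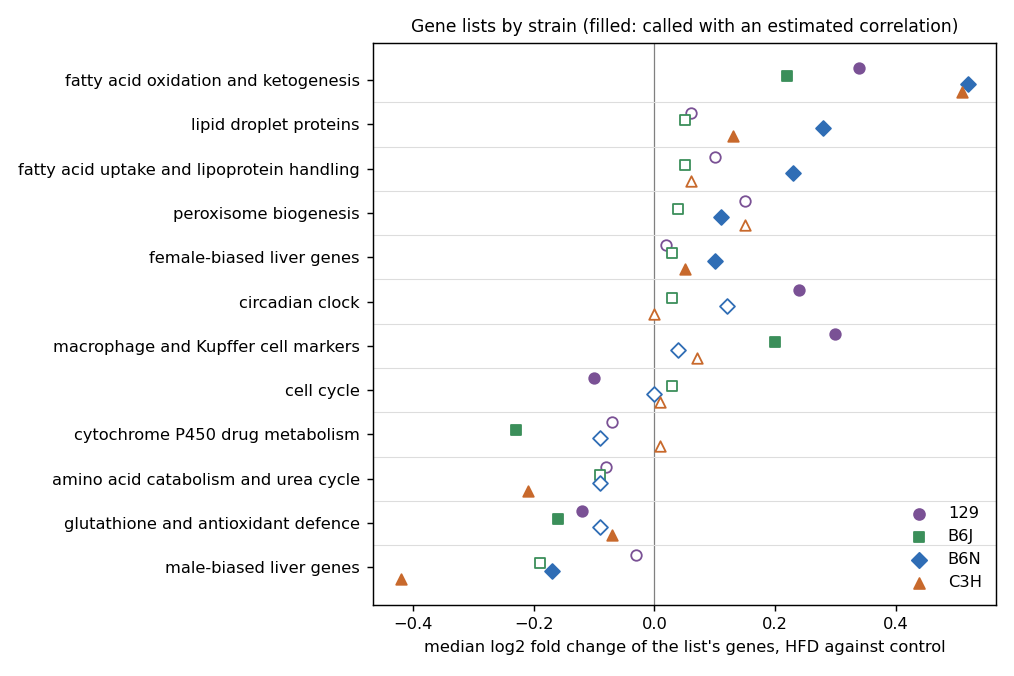
Median log2 fold change (HFD against control) of the measured genes of 12 lists in each strain (symbols). Filled symbols mark lists that camera called with an estimated correlation. Fatty acid oxidation lay between 0.22 and 0.52 in the 4 strains and was called in each, while the clock list was called so in 129 (median 0.24) and stood at 0 in C3H.

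In 129 livers, fatty acid oxidation, clock and macrophage genes were higher and glutathione genes lower on HFD. Vnn1 rose 4.50-fold (95% interval 3.15 to 6.43; n = 8 and 7), from 8.21 ± 0.675 to 10.38 ± 0.672 (SD), and all 7 HFD arrays lay above every control. Dio1 rose 3.82-fold (2.67 to 5.47), Ciart, a clock repressor, 2.89-fold (1.81 to 4.62), and Lcn2 2.13-fold (1.55 to 2.93). Cyp4a14 and Cyp4a31 rose by 2.09 ± 0.49 and 1.18 ± 0.29. Etnppl fell 2.47-fold (1.82 to 3.34), Cyp3a44 2.39-fold (1.89 to 3.04) and Cyp3a11, the main P450 of drug oxidation in mouse liver, 2.09-fold (1.61 to 2.71). Gstm3 (-1.01 ± 0.20) and Cyp2c55 (-1.0 ± 0.21) were lower in all 7 HFD arrays than in any control, and the lipase gene Mgll (0.75 ± 0.15) was higher in all 7. Cyp2c55 lay below the array medians in both groups (6.07 and 5.07).

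In 129, 7 of 35 fatty acid oxidation genes rose (15 adjusted over the list alone; camera adjusted p = 6.4e-27; 0.0021 with an estimated correlation), among them Eci2, an isomerase of unsaturated fatty acids (0.57 ± 0.11). Of 25 macrophage markers 6 rose (13 adjusted over the list alone; 5.4e-15; 0.00074), including Adgre1 (0.97 ± 0.22), Cd5l (0.79 ± 0.16) and the complement genes C1qb (0.77 ± 0.18) and C1qc (0.75 ± 0.15). Markers of other cell types were also called higher by camera, though not with an estimated correlation: lymphocyte (1 higher of 20, 2 adjusted over the list alone; 0.0063 and adjusted p = 0.18 with an estimated correlation), stellate cell (0 of 27 called by limma, 2 over the list alone, 2 at unadjusted p under 0.05; 0.033 and 0.12), adipocyte (0 of 10, 1 and 1; 0.041 and 0.1) and acinar (0 of 16, 0 and 0; 0.036 and 0.75). The lymphocyte gene was Ptprc, which encodes CD45 (0.66 ± 0.17, adjusted p = 0.038). Of 19 clock genes 3 rose (8 higher and 1 lower adjusted over the list alone; 3.7e-07; 0.022): Ciart, Per3 (0.91 ± 0.22) and Per2 (0.59 ± 0.14). Of 35 glutathione genes 4 fell (5 adjusted over the list alone; 3.6e-09; 0.022), including Gstm6 (-0.63 ± 0.13), Gstm4 (-0.62 ± 0.13) and Gsta4 (-0.57 ± 0.10). Cell cycle genes had a median change of -0.10 with 0 of 25 called by limma (0 adjusted over the list alone, 4 at unadjusted p under 0.05; 0.0012; 0.029). That list was not called with bright genes only (adjusted p = 0.056, and 0.13 with an estimated correlation), and with an estimated correlation its call was lost with quantile normalisation (adjusted p = 0.1). The clock call with an estimated correlation was lost with bright genes only (0.089) and without 129 control replicate 6 (adjusted p = 0.06), while the preset call without that array was kept (4.5e-05).

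In all, 115 genes changed in 129, 88 higher and 27 lower. With array weights 576 were called (357 higher and 219 lower). With quantile normalisation the split was 73 higher and 54 lower, and Cyp2c55 was no longer called (adjusted p = 0.12). With only the 129 arrays in the fit 41 genes were called, and Cyp4a14, Dio1, Ciart, Cyp4a31, Lcn2, Adgre1, Per3, Per2, Etnppl, Cd5l, C1qb and C1qc were not (adjusted p 0.06 to 0.33). Ptprc was not called with quantile normalisation, median centring, every probe set or only the 129 arrays (0.061 to 0.12), or without control 1, 2, 4, 5, 7 or 8 or HFD 1, 3, 4, 6 or 7 (0.053 to 0.26). Single arrays also decided other calls. Adgre1 was lost without HFD replicate 6 (log2 change 0.60, adjusted p = 0.11), which left 69 genes in all, and C1qb without control 1 or HFD 1, 3 or 6 (0.053 to 0.14). Cyp4a14 was lost without control 6 or 7 or HFD 1 or 2 (0.057 to 0.08), Cyp4a31 without control 6 or 7 or HFD 2, 3 or 7 (0.055 to 0.17), Per3 without control 4, 6, 7 or 8 or HFD 1, 2 or 3 (0.06 to 0.14), and Per2 without control 6 or 8 or HFD 2, 3 or 5 (0.058 to 0.089).

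In B6J livers, Mfsd2a rose 7.89-fold on HFD (95% interval 4.46 to 13.9; n = 8 and 7), from 6.24 ± 0.635 to 9.22 ± 0.396 (SD). Apoa4 rose 3.21-fold (2.58 to 3.98) and Fabp2 3.04-fold (2.19 to 4.23). Cyp17a1, a steroid hydroxylase, rose 2.65-fold (1.98 to 3.54), Serpina7, the thyroxine-binding globulin, 2.45-fold (1.69 to 3.53), and Vnn1 2.38-fold (1.66 to 3.40). Csad fell 2.58-fold (1.86 to 3.59), Cyp2c55 2.57-fold (1.92 to 3.45), the zinc importer gene Slc39a4 2.44-fold (1.74 to 3.43) and Cyp3a44 2.30-fold (1.82 to 2.92). Slc13a2 (-1.17 ± 0.16) and the carboxylesterase gene Ces2a (-0.98 ± 0.11) were lower in all 7 HFD arrays than in any control. On HFD, Cyp2c55 and Slc13a2 lay below the array medians (4.49 and 3.90). Fads2 (0.96 ± 0.19) and Mgll (0.85 ± 0.15) rose.

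Of 35 glutathione genes in B6J 5 fell (13 adjusted over the list alone; camera adjusted p = 2.7e-14; 0.0033 with an estimated correlation), including Gstm3 (-0.94 ± 0.20), Gsta4 (-0.91 ± 0.10) and Gstp1 (-0.68 ± 0.13). Of 26 P450 genes 2 fell (3 adjusted over the list alone; 4.4e-08; 0.019), Cyp2c55 and Cyp3a11 (-0.79 ± 0.19). Of 35 fatty acid oxidation genes 3 rose (11 adjusted over the list alone; 1e-15; 0.022). Limma called 0 of 25 macrophage markers (3 adjusted over the list alone, 7 at unadjusted p under 0.05), whose median shifted by 0.20 (2e-07; 0.022). Mature hepatocyte markers had a median of -0.11 in B6J (0 of 18 called by limma, 0 adjusted over the list alone, 2 at unadjusted p under 0.05; 0.00022 and adjusted p = 0.24 with an estimated correlation). Fatty acid uptake genes had 2 members higher of 23 (4 higher and 1 lower adjusted over the list alone; 0.00026 and adjusted p = 0.078 with an estimated correlation).

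In all, 59 genes changed in B6J, 26 higher and 33 lower, and 38 without control replicate 5. The split was 39 and 38 with quantile normalisation, 72 and 57 with array weights (129 genes) and 42 and 53 with only the B6J arrays in the fit (95 genes). Cyp3a11 was the least secure of those named, with its call lost in 12 fits without 1 array: control 1, 2, 3, 4, 5, 7 or 8, or HFD 1, 2, 4, 6 or 7 (adjusted p 0.052 to 0.088), and with every probe set as a test (0.059). With the 2 parts of the B6 arrays as a block 57 genes were called. Within part 1 (4 controls, 5 HFD) 21 were called and within part 2 (4 controls, 2 HFD) 4, and of the B6J genes named here Serpina7, Vnn1, Fads2, Slc39a4, Gstm3, Mgll, Gstp1 and Cyp3a11 were called in neither part.

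In B6N livers, Cyp2b9, a female-biased P450, rose 8.13-fold on HFD (95% interval 4.64 to 14.3; n = 8 and 8), from 4.11 ± 0.735 to 7.13 ± 2.01 (SD), with 6 of 8 HFD arrays above every control. The control level lay below the array medians (4.52 to 4.67), where signal cannot be told from background, so the size of this fold is uncertain. The interval uses the spread shared by all groups. SDs of Cyp2b9 ran from 0.123 in 129 controls to 2.01 in B6N HFD livers, so the interval is too narrow for the spread in B6N. Rgs16 rose 7.93-fold (4.08 to 15.4), Apoa4 4.71-fold (3.82 to 5.81), Mfsd2a 4.71-fold (2.71 to 8.16), Cyp4a14 4.58-fold (2.38 to 8.79) and Vnn1 3.71-fold (2.63 to 5.23). Fgf21, a liver hormone of fasting and nutrient stress, rose 2.57-fold (2.02 to 3.26). Cyp7a1 fell 4.34-fold (2.50 to 7.56), Cyp2c55 3.42-fold (2.57 to 4.53), Csad 3.04-fold (2.21 to 4.18), Cyp3a44 2.78-fold (2.21 to 3.50) and Acmsd 2.64-fold (2.06 to 3.39). Cyp3a11 fell by 1.08 ± 0.18 on the log2 scale. Cyp2c55 lay below the array medians on HFD (4.40).

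Fatty acid oxidation was the list with the most called members in B6N: 24 of 35 rose (31 adjusted over the list alone; camera adjusted p = 3.1e-76; 2e-07 with an estimated correlation). Of 19 lipid droplet genes 3 rose (10 adjusted over the list alone; 4.6e-17; 7.1e-06), the droplet fusion gene Cidec (1.04 ± 0.16), Mgll (1.02 ± 0.15) and Plin2 (0.76 ± 0.12). Of 23 fatty acid uptake genes 7 rose (10 higher and 1 lower adjusted over the list alone; 1.3e-16; 3.8e-05), including Fabp2 (1.33 ± 0.23) and Mogat1, of triglyceride synthesis (0.90 ± 0.14), which lay below the array medians in both groups (3.49 and 4.38). Of 25 male-biased genes 6 fell (10 adjusted over the list alone; 2.9e-12; 0.0098), including Selenbp2 (-1.05 ± 0.23), Gstp1 (-0.94 ± 0.13) and C8b (-0.87 ± 0.13). Of 22 female-biased genes 5 rose and 1 fell (8 and 2 adjusted over the list alone; 4.8e-05; 0.022), including Abcd2 (1.76 ± 0.30) and Cyp17a1 (1.39 ± 0.20). Peroxisome genes had 1 member higher of 17 (5 adjusted over the list alone; 1.3e-05; 0.048). With the replicate block, the calls with an estimated correlation were lost for the female-biased list (adjusted p = 0.072) and the peroxisome list (adjusted p = 0.058), as with bright genes only (0.19 and 0.13).

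The glutathione transferase Gsta4 (-1.11 ± 0.09) fell in B6N, although 2 of its 35 list members were called lower (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00022 and adjusted p = 0.2 with an estimated correlation). Fads2 (1.15 ± 0.18) and Elovl5 (1.0 ± 0.15) rose, the 2 called members of 24 fatty acid synthesis genes (5 adjusted over the list alone; 1.4e-07 and adjusted p = 0.24 with an estimated correlation). The acinar genes moved with diet by a median of 1.19, with 0 of 16 called by limma (0 adjusted over the list alone, 4 at unadjusted p under 0.05; 2.5e-06 and adjusted p = 0.38 with an estimated correlation). In all, 183 genes changed in B6N, 127 higher and 56 lower. With the B6 split as a block 222 were called, within part 1 (4 controls, 3 HFD) 39 and within part 2 (4 controls, 5 HFD) 86. Selenbp2 was called in neither part and not with only the B6N arrays in the fit (adjusted p 0.097 to 0.16), and Rgs16, Mfsd2a, Cyp4a14, Vnn1, Abcd2, Cyp7a1, Fads2, Elovl5, Fgf21, Plin2 and Cyp3a11 were not called within part 1 (adjusted p 0.057 to 0.83).

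In C3H livers, HFD raised Cyp4a14 12.1-fold (95% interval 6.93 to 21.0; n = 18 and 8), from 2.94 ± 0.337 to 6.53 ± 0.786 (SD), and Cyp2b9 11.2-fold (6.98 to 18.1). Vnn1 rose 7.07-fold (5.27 to 9.47), Cyp4a31 6.00-fold (4.30 to 8.37), Mfsd2a 5.41-fold (3.39 to 8.63) and Cyp4a10 4.52-fold (3.38 to 6.06). The control levels of Cyp4a14 and Cyp2b9 (2.94 and 2.62) lay below the array medians (3.10 to 3.28), where signal cannot be told from background, so the sizes of these 2 folds are uncertain. For Cyp4a14, Vnn1, Cyp4a31 and Cyp4a10, all 8 HFD arrays lay above every control. Cd36 rose 3.27-fold (2.39 to 4.47) and Abcd2 2.96-fold (2.09 to 4.19). Etnppl fell 2.90-fold (2.26 to 3.72), Cyp7a1 2.88-fold (1.80 to 4.62) and Acmsd 2.25-fold (1.82 to 2.78), and Lpl, the lipoprotein lipase gene, fell 1.99-fold (1.64 to 2.41). Cyp3a11 (0.61 ± 0.16) and Cyp3a44 (0.53 ± 0.14) rose, with 2 and 3 of 8 HFD arrays above every control.

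Of 35 fatty acid oxidation genes in C3H 19 rose (31 adjusted over the list alone; camera adjusted p = 4.1e-76; 2e-07 with an estimated correlation). Of 25 male-biased genes 7 fell (14 lower and 1 higher adjusted over the list alone; 1.2e-19; 0.00074), including Cyp7b1 (-0.83 ± 0.15) and the complement genes C8b (-0.74 ± 0.11) and C6 (-0.73 ± 0.15). Of 22 female-biased genes 4 rose and 1 fell (6 and 2 adjusted over the list alone; 0.00023; 0.037). Of 29 amino acid catabolism genes 8 fell (13 adjusted over the list alone; 1.2e-19; 0.0077), including Cth (-0.65 ± 0.10) and Cps1, of the urea cycle (-0.48 ± 0.10). Beside this, mature hepatocyte markers had 1 member lower of 18, again Cps1 (3 adjusted over the list alone; 0.00039 and adjusted p = 0.25 with an estimated correlation), endothelial markers (median -0.09) 0 of 20 called by limma (0 over the list alone, 3 at unadjusted p under 0.05; 0.005 and 0.39) and skeletal muscle markers (median -0.17) 0 of 14 (0 and 0, 0.013 and 0.64). Of 19 lipid droplet genes 5 rose (6 adjusted over the list alone; 2.6e-08; 0.0024), including Fitm1 (0.79 ± 0.15), Mgll (0.78 ± 0.13) and Plin2 (0.68 ± 0.10). Of 35 glutathione genes 6 fell (8 adjusted over the list alone; 1.9e-09; 0.022), including Gstm3 (-0.85 ± 0.16), Gstp1 (-0.73 ± 0.11) and Gsta4 (-0.61 ± 0.08). Fatty acid uptake genes went both ways, 4 higher and 2 lower of 23 (6 and 2 adjusted over the list alone; 0.008 and adjusted p = 0.22 with an estimated correlation), with Apoa4 (1.30 ± 0.13) and Fabp2 (1.02 ± 0.20) higher and Fabp5 (-1.04 ± 0.23) lower.

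In all, 170 genes changed in C3H, 103 higher and 67 lower, against 295 with quantile normalisation, 105 with array weights and 93 with only the C3H arrays. Of 100 splits of the 26 C3H arrays into groups of these sizes, 6 called as many genes, so the count alone does not exclude chance. Cyp3a11 was not called with array weights, with only the C3H arrays in the fit, with every probe set as a test, or without control 15 or 16 or HFD 6, 7 or 8 (adjusted p 0.05 to 0.4). Cyp3a44 (adjusted p = 0.046) was not called with quantile normalisation (0.07), median centring (0.072) or array weights (0.46), or without control 1, 5 or 12 to 18 or HFD 1, 2, 3, 5, 6, 7 or 8 (0.053 to 0.14). With bright genes only, the glutathione and female-biased calls with an estimated correlation were lost (adjusted p = 0.077 and 0.19). Cyp7a1, Fabp5 and Cyp7b1 were not called with array weights (0.062 to 0.071), nor Gstm3 and Cps1 with only the C3H arrays (0.057 and 0.13).

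**Figure D3:**
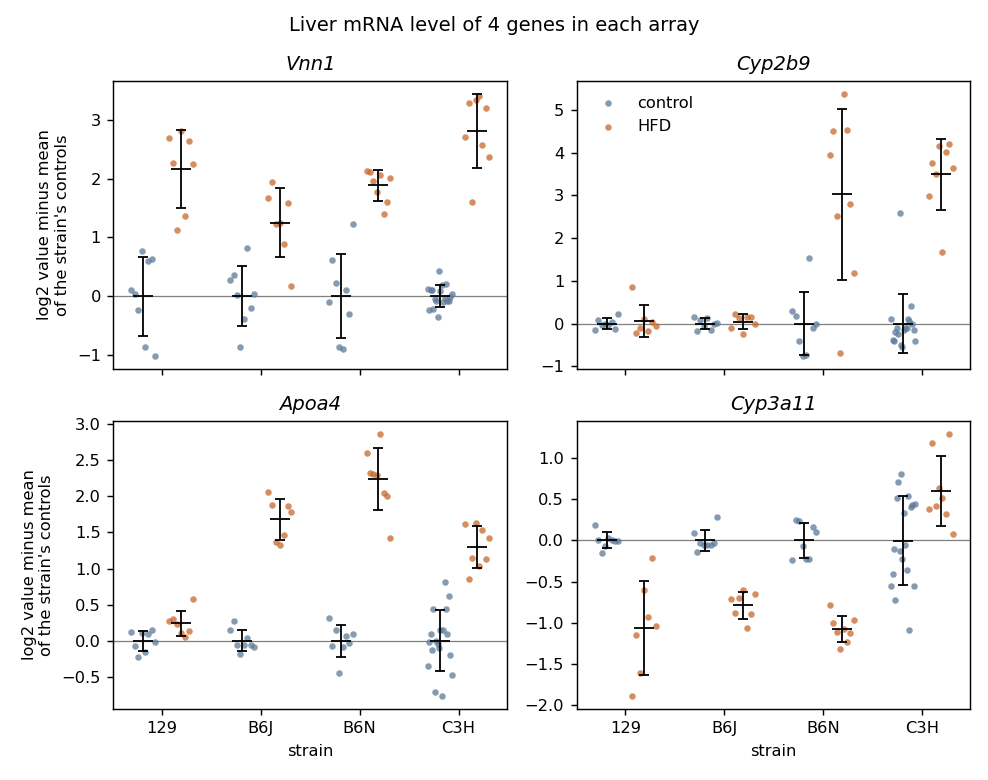
Log2 signal of Vnn1, Cyp2b9, Apoa4 and Cyp3a11 in each array (points) minus the mean of the controls of its strain, with group mean and SD (bars). HFD means ran from 1.25 to 2.82 for Vnn1, stood at 0.07 and 0.04 for Cyp2b9 in 129 and B6J against 3.02 and 3.49 in B6N and C3H, and had the opposite sign for Cyp3a11 in C3H.

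A set of 9 genes changed in all 4 strains in 1 direction, 4 higher and 5 lower. The count was 20 with quantile normalisation (9 and 11) and 24 with array weights (17 and 7), and 5 genes passed at 1.5-fold. Vnn1, Mgll, the signalling adaptor Stap1 and the lactate dehydrogenase gene Ldha rose. Ddc, Slc13a2, Gsta4, Ethe1, a mitochondrial sulfur dioxygenase, and Ces2a fell. Independent lists of these sizes would share 3.78e-06 genes higher and 4.22e-07 lower. Their mean changes were 2.03 ± 0.12 for Vnn1, 0.85 ± 0.07 for Mgll, 0.85 ± 0.08 for Stap1, 0.41 ± 0.04 for Ldha, -0.81 ± 0.05 for Ces2a and -0.68 ± 0.07 for Ethe1. Stap1 lay below the array medians on both diets in B6J (3.43 and 4.27) and B6N (3.45 and 4.35). Slc13a2 lay below them on HFD in 129, B6J and B6N (6.19, 3.90 and 3.83). The sizes of these changes are therefore uncertain. Of the 359 genes called in any strain, 173 were called higher and 78 lower in 1 strain. In 2 strains 43 were higher and 20 lower, in 3 strains 23 and 15, and in all 4 strains 4 and 5. Calls overlapped most in number between C3H and B6N, with 58 genes higher and 25 lower in both against 0.656 and 0.188 for independent lists. B6N and B6J shared 25 and 20 (0.166 and 0.0927), C3H and B6J 19 and 14 (0.134 and 0.111), C3H and 129 14 and 12 (0.455 and 0.0907), B6N and 129 14 and 12 (0.561 and 0.0758), and B6J and 129 6 and 12 (0.115 and 0.0447). Only 2 genes, Cyp3a11 and Cyp3a44, were called in opposite directions in different strains. The strains share no arrays but do share 1 variance estimate.

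The HFD effect differed between strains for 25 genes by the moderated F test. Cyp3a44 changed by -1.26, -1.20, -1.48 and 0.53 in 129, B6J, B6N and C3H (adjusted p = 1.3e-10), and Cyp3a11 by -1.06, -0.79, -1.08 and 0.61 (5.3e-07). Apoa4 changed by 0.24, 1.68, 2.24 and 1.30 (1.8e-08), and Cyp2b9 by 0.07, 0.04, 3.02 and 3.49 (1.2e-06). In 129 and B6J, Cyp2b9 lay below the lower quartile of the arrays on either diet (4.66 and 4.72, 3.30 and 3.34), so a small change there could not be seen. Cyp17a1 changed by 0.30, 1.40, 1.39 and -0.03 (0.00058), and Lpl by 0.25, -0.12, -0.13 and -0.99 (0.0043). In C3H, Cyp17a1 lay at the level of the array medians on either diet (3.276 and 3.245), so a small change there may have been missed. The annexin gene Anxa2 had effects of 0.28, 0.42, 0.91 and 0.08 (0.0031), Ces2a of -0.69, -0.98, -1.19 and -0.36 (0.0038), Cyp2c55 of -1.0, -1.36, -1.77 and -0.29 (0.0065), and Cyp4a10 of 0.73, 0.51, 1.19 and 2.18 (0.012). With the replicate number as a block, 6 genes were called by F, and Cyp17a1, Lpl, Anxa2, Cyp2c55 and Cyp4a10 were not (adjusted p 0.08 to 0.094). Cyp4a10 was also lost with quantile normalisation (0.063). The count was 38 without 129 HFD replicate 2 and 71 with array weights. Effects of 1 sign in separately normalised sets can also differ through unequal compression, which was examined for Cyp3a11 and Cyp3a44 only and leaves differences of size, as in Apoa4, Ces2a, Anxa2, Cyp2c55 and Cyp4a10, with this limit.

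By pairs of strains, limma called 12 genes between C3H and 129. Cyp2b9 (difference of log2 effects 3.43 ± 0.54), Cyp3a44 (1.79 ± 0.22) and Cyp3a11 (1.67 ± 0.24) had the higher effect in C3H, and Lpl (-1.24 ± 0.22) and the nucleic acid receptor gene Tlr13 (-0.94 ± 0.18) the lower. Without 129 HFD replicate 2 or with array weights this count was 24, and Tlr13 was not called with only these groups in the fit (adjusted p = 0.095). Between C3H and B6N 9 genes differed, led by Cyp3a44 (2.0 ± 0.22), Cyp3a11 (1.69 ± 0.24), Cyp2c55 (1.49 ± 0.27) and Cyp17a1 (-1.43 ± 0.27). The effect was higher in C3H for 5 of them and lower for 4, against 7 and 3 with quantile normalisation and 4 and 5 with median centring. With the replicate block 5 were called, and Cyp17a1 was lost (adjusted p = 0.23), as with array weights (0.17). Its low level in C3H, at the array medians, also limits this difference. Between C3H and B6J 8 differed, among them Cyp2b9 (3.45 ± 0.54), Cyp4a31 (2.16 ± 0.38), Cyp3a44 (1.73 ± 0.22) and Cyp3a11 (1.39 ± 0.24).

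Between B6N and 129, 8 genes differed, led by Cyp2b9 (2.96 ± 0.58), Apoa4 (1.99 ± 0.22) and Elovl5 (1.14 ± 0.22). Without 129 HFD replicate 3 or 6 the count was 5 without B6N HFD replicate 8 it was 18 and with array weights 73, and Cyp2b9 was not called with only these groups in the fit (adjusted p = 0.24). Between B6J and 129, Apoa4 alone was called (1.44 ± 0.22, adjusted p = 0.00021), against 1 gene in each direction after median centring, and the count was 2 without 129 control 5, 129 HFD 3, 6 or 7, or B6J HFD 6. Between B6N and B6J limma called 0 genes at the adjusted threshold and 608 at an unadjusted p under 0.05. The nearest was Cyp2b9 (2.98 ± 0.58, adjusted p = 0.052), and 1 gene was called with the replicate block or without B6N control 2 or B6N HFD 4 or 8. No gene list differed between strains in its HFD effect with an estimated correlation, where the lowest adjusted p was 0.06.

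In control livers, 7 genes differed between B6N and B6J. Besides Nnt, which was 2.20-fold higher in B6N (95% interval 1.73 to 2.79), Acnat2, an acyltransferase of fatty acid conjugation, was 3.24-fold higher (2.28 to 4.6) and Wdfy1 1.80-fold higher (1.54 to 2.11). The B6J level of Acnat2 (3.41) lay at the lower quartile of the arrays (3.41 to 3.48), where signal cannot be told from background, so the size of that fold is uncertain, and G530011O06Rik lay below the array medians in B6N (4.19). Entpd4, a nucleotide hydrolase of the Golgi (-0.70 ± 0.09), G530011O06Rik (-1.05 ± 0.16), Tmem267 (-1.05 ± 0.16) and Itih5 (-0.69 ± 0.14) were lower in B6N. Itih5 was not called without B6J control 3, 7 or 8 or B6N control 2, 3, 4 or 6 (adjusted p 0.062 to 0.21), with quantile normalisation (0.058), with the acinar level as covariate (0.077) or with only these groups in the fit (0.33). Within part 1 of the B6 arrays Nnt (adjusted p = 0.13) and Itih5 were not called, and within part 2 Entpd4 alone was.

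Cholesterol synthesis genes lay lower in B6N than in B6J controls by a median of -0.42. Limma called 0 of 20 over all genes, 13 adjusted over the list alone and 14 at an unadjusted p under 0.05 (camera adjusted p = 6.5e-20; 0.025 with an estimated correlation). Endoplasmic reticulum stress genes had a median of -0.20, with 0 of 27 called, 6 adjusted over the list alone and 10 unadjusted (2.3e-12; 0.012). The acinar genes had a median of -2.01, with 0 of 16 called, 14 adjusted over the list alone and 14 unadjusted (8.5e-16 and adjusted p = 0.21 with an estimated correlation). The control lists were not fitted with the acinar level as a covariate. Whether this acinar difference bears on the differences of the other lists was not tested. Endothelial markers (median -0.11, 0 of 20 called, 0 over the list alone, 4 unadjusted, camera adjusted p = 0.014) and mature hepatocyte markers (median -0.07, 0 of 18, 0 and 5, camera adjusted p = 0.0026) were also lower by camera, with adjusted p = 0.42 and 0.4 with an estimated correlation.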

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

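The tests of diet effects and of their differences between strains were planned, and the correlation of islet genes with the acinar level was set up before its result was seen. The other tests of explanations and the splits of the arrays were chosen after the results they bear on were seen.

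The level of pancreatic acinar genes varied up to 81.6-fold between livers of 1 group (B6J controls), and pancreatic tissue carried over at dissection is a candidate source. The islet genes Ins2, Gcg and Iapp, which are outside the acinar list, followed the acinar level over the 15 arrays of strain 129 (Pearson r = 0.689, permutation p = 0.00201, adjusted over 4 strains 0.00402, Spearman rho = 0.593, p = 0.0227, adjusted 0.085, r = 0.54 without the 2 farthest arrays), where Ins2 spanned log2 values from 5.70 to 6.90. Gcg (5.25 to 6.47) and Iapp (4.57 to 5.15) lay at or below the array medians of 129 (6.46 to 6.65). Gcg in B6J also lay below the medians (3.155 to 4.027). Such levels cannot be told from background, which limits these correlations. In B6J r was 0.822 (permutation p = 0.00019, adjusted 0.00076, rho = 0.536, p = 0.0425, adjusted 0.085, r = 0.608 without the 2 farthest), and 0.812 and 0.842 within the 2 parts of the B6 arrays (exact p = 0.00716 and 0.075). In B6N (r = 0.043, permutation p = 0.874, rho = -0.0147, p = 0.96, r = 0.427 without the 2 farthest) and C3H (r = 0.221, p = 0.281, rho = 0.307, p = 0.127, r = 0.321 without the 2 farthest), whose acinar ranges were narrower, the tests did not pass, which does not show that no relation exists. The islet genes all lay below the array medians in B6N (highest value 4.063, Ins2) and at or below them in C3H (highest value 3.179, Ins2). A relation could therefore have been missed in these strains. A response to HFD was not the source of the spread among controls, which had no HFD and spanned 6.35 log2 units in B6J, but as part of the difference in B6N (1.23, exact permutation p = 0.0135, adjusted 0.054) it stays open.

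Cyp3a11 and Cyp3a44 fell on HFD in 129, B6J and B6N and rose in C3H. Unequal compression of fold changes in the 3 separately normalised sets would keep 1 sign, but the 95% intervals in C3H began at 0.30 and 0.25 and those in B6N ended at -0.72 and -1.15. The C3H intervals began at 0.04 and 0.11 with the replicate block, and at 0.17 and 0.14 with array weights. In C3H, 2 of 8 HFD arrays lay above every control for Cyp3a11 and 3 of 8 for Cyp3a44. Relative to the control mean, Cyp3a11 ran from -1.09 to -0.131 in controls 12 to 18 and from 0.339 to 0.807 in controls 6 to 11. HFD arrays 1 to 5 (0.083 to 0.513) lay within the range of the controls. Whether this order among the controls bears on the rise was not tested. No single C3H array decided the difference from B6N, with an adjusted p of at most 5.6e-05 without 1 C3H array (range over all alternatives 2e-06 to 0.00055 for Cyp3a11 and 6.9e-10 to 3.8e-06 for Cyp3a44), although the C3H change of Cyp3a11 taken alone lost its call without any of 5 arrays (adjusted p 0.051 to 0.13) and that of Cyp3a44 without any of 16 (0.053 to 0.14). Signal shared between both genes cannot be told apart from separate changes, since they moved alike in every strain, while 0 of the 4 other Cyp3a genes measured (Cyp3a13, Cyp3a16, Cyp3a25 and Cyp3a57) had a called interaction. A strain difference in the response stays open as a hypothesis.

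Clock genes were higher on HFD in 129. Collection of the groups at different clock times may account for this, and no collection time was found in the labels. Genes of the opposite phase (Arntl, Clock, Cry1 and Nfil3) differed by a mean of -0.26 (exact permutation p = 0.14), which left it open. This mean came mostly from Arntl (-0.77), against -0.15 for Clock, -0.06 for Cry1 and -0.07 for Nfil3. Npas2 was also named for this test but was not part of the mean. Control replicate 6, whose values stood apart, was not the whole cause by the preset test, since the list kept a camera adjusted p of 4.5e-05 without it (range over the alternatives 8.4e-08 to 0.00017), but with an estimated correlation the call was lost (adjusted p = 0.06, range 0.0028 to 0.089). An effect of diet on the clock in this strain stays open and was not tested apart from clock time.

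Some arrays lay far from the rest of their group by Dixon's ratio, in 16 of 192 groups of values tested, where chance alone flags about 1 in 20, or 9.6. 129 control replicate 6 had the highest median (6.653) and lower quartile (5.276) and the lowest upper quartile (8.046) of its group, and the lowest Cyp4a31 value (7.58). 129 HFD replicate 6 had the lowest Gsta4 (10.94) and the highest Adgre1 (11.11). B6J HFD replicate 3 had the highest lower quartile (3.505) and the lowest Slc39a4 (5.70). Cyp2c55 was highest in B6J HFD replicate 5 (5.32) and Gstp1 in B6J HFD replicate 6 (12.87). In B6N, control replicate 2 was highest for Cyp2b9 (5.65), control replicate 4 for Rgs16 (7.23) and Plin2 (11.54), and HFD replicate 8 for Selenbp2 (11.41). B6N HFD replicate 8 was lowest for Cyp4a14 (9.94) and B6N control replicate 8 for Gsta4 (9.87).

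HFD effects differed between strains, by the test of the difference itself, for 25 genes over all strains. By pairs the counts were 1 for B6J against 129, 8 for B6N against 129, 12 for C3H against 129, 8 for C3H against B6J and 9 for C3H against B6N.

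Among the 13767 probe sets without a single gene symbol, which the report does not use, 28 were called for HFD in 129, 13 in B6J, 34 in B6N, 36 in C3H and 108 in the mean effect.

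Other splits of the same arrays into groups of the same sizes were counted, 100 per comparison with the real one included. No other split gave as many for the mean effect (630 genes, highest other split 1), 129 (115, 67), B6N (183, 36) or genes called in all 4 strains (9, 0). In each, 1 of 100 splits, the real one, gave as many, the lowest share this test can give. These shares were not adjusted over the comparisons. For B6J 3 splits gave as many (59, highest other 1579), a share under 0.05 for this comparison alone, although the highest other was far above the real count. For C3H 6 did (170, highest other 3530), a share above 0.05. Splits that call 1579 or 3530 genes point to structure among the B6J and C3H arrays. After that result, the main axis of the C3H controls, with 27.8% of their variance (r = 0.756 with Malat1), was taken as a covariate, and HFD arrays scored -2.48 on it (SD 18.7) against 0 (SD 19.4). With it 232 genes were called and the highest other split had 202, with 1 of 100 as large. With the B6 split as a block, B6J gave 57 and the highest other 7 (1 of 100), and with B6N numbers kept paired, the highest other gave 103 for B6N, 45 for the mean effect and 0 for genes called in all 4 strains (1 of 100 each). The C3H axis came from the real controls and the B6 split from residuals about the real group means. Both were kept unchanged in every split. The shares with the axis and with the B6 block thus favour the real labels and do not exclude chance.

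For the interactions, the mean HFD effect of each gene was subtracted from the HFD arrays before they were split. This leaves the differences between strains in the real split unchanged. Splits that did not keep B6N pairs were counted first. No other split gave as many genes for the F test (25, highest other 8) or B6N against 129 (8, 4). The same held for C3H against 129 (12, 3) and C3H against B6N (9, 7), with 1 split of 100, the real one, in each. For C3H against B6J 2 gave as many (8, highest other 25) and for B6J against 129 3 did (1, highest other 1), shares under 0.05 for each comparison alone, with no adjustment over the comparisons. With B6N numbers kept paired, 1 split of 100 gave as many for B6N against 129 (highest other 1), 2 did for C3H against B6N (highest other 25) and 3 for the F test (highest other 100), so for both of the latter some splits called far more genes than the real one. For B6N against B6J all 100 gave at least the 0 genes limma called (608 at unadjusted p under 0.05), with a highest other of 4, or 1 with B6N numbers kept paired (100 of 100). For B6N against B6J controls no other split gave as many (7, highest other 5, 1 of 100).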

How the results depend on the processing

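The settings with the B6 split, the acinar level, the C3H axis and without arrays that stand apart were chosen after the data were seen, and the others were planned. No called change of a named gene or list reversed under the settings it was run with, and the cause of the changes below was not tested. The test of any strain difference among controls and the 5 control comparisons between separately normalised sets were not run. The number of arrays limits precision, and without detection calls low signals cannot be told from background.

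Counts that moved by more than 1.5 times were these. Quantile normalisation gave 295 genes in C3H and 20 called in all 4 strains. Median centring gave 2 for B6J against 129. Genes above the median level gave 5 for B6N against 129. Every probe set gave 2 (B6J against 129), 15 (B6N against 129), 19 (C3H against 129) and 27 (control B6N against B6J), and the mean of a gene's probe sets 3 for B6J against 129. Array weights gave 576 in 129, 129 in B6J, 105 in C3H and 24 in all 4 strains, and for interactions 71 by F, 6 (B6J against 129), 73 (B6N against 129), 24 (C3H against 129), 2 (B6N against B6J) and 4 (C3H against B6J). A change of at least 1.5-fold left 63 in 129, 103 in B6N, 71 in C3H, 66 in the mean effect and 5 in all 4 strains. Only the compared groups in the fit gave 41 in 129, 95 in B6J, 93 in C3H, 2 (B6J against 129) and 4 (B6N against 129).

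The replicate block gave 1 for B6N against B6J, 5 for C3H against B6N and 6 by F. Within 1.5 times, it gave 105 genes in 129, 60 in B6J, 202 in B6N, 243 in C3H and 655 in the mean. In B6N, where the rule fixed in advance treats the numbers as pairs, it ended the calls of Igfbp1 (adjusted p = 0.076) and Khk (0.066) and of no other gene named by the rule. List calls lost with it were stellate cell and adipocyte markers in 129, clock genes in B6J, and endoplasmic reticulum stress, endothelial and hepatocyte genes in C3H, and in all it ended 45 of 282 named gene calls. With it the adjusted p was 0.05 for Cyp4a14, 0.075 for Adgre1 and 0.052 for Per2 in 129, and 0.33 for Cyp3a11 (log2 0.33), 0.2 for Cyp3a44 (0.40), 0.078 for Fabp5 and 0.053 for Cps1 in C3H. Of 29 list calls with an estimated correlation it ended 9: cell cycle in 129 (0.065), fatty acid oxidation and macrophage in B6J (0.058 each), female-biased and peroxisome in B6N, glutathione, female-biased and amino acid in C3H (0.19, 0.23 and 0.17) and amino acid in the mean. Bright genes only ended 8.

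Of the added settings, these moved counts by more than 1.5 times. The B6 split as a block gave 1 for B6N against B6J. The acinar level gave 2 for B6J against 129, and both together gave 187 in 129 and 2 for B6J against 129. Part 1 of the B6 arrays gave 21 in B6J and 39 in B6N, and part 2 gave 4, 86 and 1 (control). The C3H axis gave 17 genes in all 4 strains. Draws of 8 of the 18 C3H controls, which were planned, gave a median of 116.5 genes (88 to 311), within 1.5 times of 170.

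Without 1 array, counts ranged from 69 to 158 in 129, 38 to 61 in B6J, 143 to 187 in B6N, 139 to 210 in C3H and 576 to 664 in the mean effect. Genes called in all 4 strains ranged from 8 to 11, the F count from 18 to 38, and the control comparison from 6 to 10. Pairs ranged from 1 to 2 (B6J against 129), 5 to 18 (B6N against 129), 9 to 24 (C3H against 129), 0 to 1 (B6N against B6J), 6 to 9 (C3H against B6J) and 7 to 11 (C3H against B6N). These ranges passed 1.5 times for 129, B6J, F and the pairs B6J against 129, B6N against 129, C3H against 129 and B6N against B6J. Of 289 named gene calls, 57 were lost without at least 1 array, 61 at 1.5-fold, 28 with array weights, 23 with every probe set, 22 with median centring, 17 with quantile normalisation, 15 without arrays that stand apart and 11 with the acinar level, and 52 of 200 were lost with only the compared groups.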

Other observations

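The test of the hypothesis in this part and the setting with the acinar level were chosen after the results were seen, while the lists, comparisons and other settings were planned. Some genes with a strain-dependent HFD effect have not been described yet. Cd44, a hyaluronan receptor gene, had effects of 0.70, 0.34, 0.27 and -0.05 in 129, B6J, B6N and C3H (F test adjusted p = 0.043, lost with the replicate block at 0.27, median centring at 0.054 and the acinar level at 0.059), with a difference of -0.75 ± 0.15 between C3H and 129 (0.0071) that was not called with the replicate block (0.079). The chemokine gene Ccl9 had effects of -0.12, -0.60, -1.17 and -0.34 (0.034, and by F 0.08 with the block, 0.1 with centring and 0.15 with the acinar level). Its difference of -1.06 ± 0.22 between B6N and 129 (0.024) was lost with median centring (0.061), with the acinar level as covariate (0.11) and without 129 HFD replicate 3 or 6, B6N control 3 or B6N HFD 5 or 6 (0.051 to 0.077). Cysltr1, a leukotriene receptor gene, had effects of 0.57, 0.03, -0.12 and 0.04 (0.014), and was lost by F with the replicate block (0.091), with quantile normalisation (0.16) and without 129 HFD replicate 1 or 6 (0.063 and 0.064). Its control and HFD means were 5.87 and 6.44 in 129, 3.49 and 3.52 in B6J, 3.55 and 3.43 in B6N, and 2.44 and 2.48 in C3H. All lay below the array medians, where signal cannot be told from background, so a small change could not be seen. Vnn3, of the Vnn1 family, had effects of 0.17, 0.19, 0.53 and 1.19 (0.043, lost with centring at 0.1 and the acinar level at 0.053), and Slco1a4 of -0.94, -0.41, -0.98 and 0.21 (0.047, lost with the block at 0.35, centring at 0.11 and the acinar level at 0.1). Both lie outside the rule for named interaction genes and were chosen after their values were seen.

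The acute phase list was called higher in 129 (2 of 26 members higher, 6 adjusted over the list alone; camera adjusted p = 0.00017 and adjusted p = 0.19 with an estimated correlation) and lower in C3H (2 members lower, 1 higher and 5 lower adjusted over the list alone; 0.00045 and adjusted p = 0.22 with an estimated correlation). The difference between C3H and 129 had a camera adjusted p of 3.3e-08, and adjusted p = 0.061 with an estimated correlation. Cholesterol synthesis genes had a median of -0.24 in 129 (0 of 20 called by limma, 3 adjusted over the list alone, 3 at unadjusted p under 0.05; 5e-06 and adjusted p = 0.25 with an estimated correlation).

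Male-biased liver genes fell and some female-biased genes rose on HFD. The hypothesis that HFD moves male liver towards the female pattern in every strain may hold in part. With an estimated correlation both lists were called in these directions in 2 of 4 strains, B6N (adjusted p = 0.0098 and 0.022) and C3H (0.00074 and 0.037). In both B6N and C3H the female-biased call was lost with the replicate block (0.072 in B6N) and with bright genes only (0.19 each). Neither list was called in 129 (0.71 and 0.85) or B6J (0.14 and 0.88). This left the hypothesis undecided, since a call missed in 129 and B6J does not show that the lists did not move there. Some female-biased members, Abcd2 and Cyp4a10 among them, are also PPARα targets. In the same list, Cyp3a44 was called lower in 129, B6J and B6N, and Lpl in C3H alone.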
